A study of Homo sapiens with 95 samples.

How the data were processed

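The series profiled the RNA of single cells that had been recorded with a patch pipette in human glioma tissue (Patch-seq, in which the content of a recorded cell is drawn into the pipette and sequenced). Per the labels' protocols, the RNA of each cell was denatured, reverse transcribed, amplified and purified with a method based on Smart-seq2, which gives full-length cDNA and carries no molecular identifiers. The counts therefore include amplification copies, and the floors and intervals given here cover counting error only. The genome build is hg38, per the submitters' processing notes. The aligner, the counting program and the gene annotation are not given in the sources used here.

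The authors deposited 1 matrix of whole-number read counts, with 14165 gene rows and 95 cell columns, per the file headers, and no normalization was applied to the values. The matrix gives row and column numbers and no names for either. Gene names were not taken from the order of the rows, and no column was matched to a sample from the order of the columns, so all 95 columns stayed without a sample and cells are named here by their column number. The labels put all 95 samples in 1 group, glioma, and give no donor, tumour type or recorded physiology. The matrix was for this reason treated as 1 pooled sample of cells. No test across cells was run, no p-value was computed, and levels are given as medians, quartiles and ranges. Electrophysiological recordings were not analysed here.

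The design fixed before the data were examined had planned marker lists for neurons, oligodendrocyte precursors and other cell types, lists of ion channels and receptors, and a rule for naming genes. These lists need gene names and were not computed. The part of that design written for a file without names was followed: depth, genes detected, the share of the leading genes and the similarity of cells. The clustering of cells was also run, without the planned removal of mitochondrial, ribosomal, sex-linked and channel genes, which needs names.

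Cells with at least 50000 counts and 1000 genes were kept, which left 93 of 95 cells. CPM values were computed by scaling each cell to a total of 1000000 over all rows. A count of 0 allows up to 3 counts, which is 0.160 to 11.6 CPM across the kept cells. If both reads of a pair were counted, which the sources do not state, the same number of fragments would be 6 counts and the floors 0.320 to 23.3 CPM. To compare genes detected across depths, each kept cell was thinned at random to 100000 counts, a depth that all 93 reached. The similarity of cells was Pearson's r across genes of log2(CPM + 1), and genes are not independent replicates. For clusters, the 2000 genes with the highest variance for their mean level, among genes at 10 CPM in at least 5 cells, were reduced to 15 principal components and joined by Ward's method. The number of clusters between 2 and 8 with the highest mean silhouette was taken. The matrix was searched for blocks of columns in 2 ways: the cut of the columns into 3 stretches with the least spread of log10 totals, and the cut at which no gene was absent from a whole stretch. Doublets were not called, since each column is a cell drawn into a pipette by hand.

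The search for blocks by absent genes, the clustering, the thinning and the ratio of low values were tested on simulated data for the 14165 genes. The search by totals and the similarity, nearest-cell and leading-gene comparisons were not. Simulated genes were kept only if detected in every stretch, so the simulated edges left no gene absent by construction. The test could only show whether another cut did the same, and none did in 5 of 5 matrices. With 200 planted genes detected in 80% of the cells of one side and 20% of the other, clustering placed 90 of 93 cells correctly, and with 500 such genes it placed all 93. With 200 genes raised 4-fold only where already detected, it placed 53 of 93, and with a 16-fold rise 71 of 93. In these simulations the clustering thus found differences in which genes were detected and placed fewer cells correctly when only levels differed. The simulated values were shuffled over cells and held no blocks and no differences in depth. They therefore do not show what the clusters of the real cells follow. Thinning was checked in the first 10 kept cells, all of the first block, where numbers of genes lay within 0.930% of the exact expectation. Cells of the other blocks were not checked. The alternatives were other detection thresholds, cell filters, numbers of variable genes and components, k-means, thinned counts and centring within blocks. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0 were used.

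The counts carry features that affect any measurement made from them. Of the 426668 values above 0, 78.9% were even numbers, and values of 2 were 9.70 times as common as values of 1. Values above 1000 were even in 72.5% of cases. The gene rows are limited to genes found in at least 3 cells. Every one of the 14165 rows is above 0 in each of the 3 blocks of columns described in the results, so a gene detected in cells of 1 or 2 blocks alone has no row.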

Results

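The RNA of 95 patched cells from human glioma, a tumour of glial origin, was counted over 14165 genes. All cells belong to 1 group in the labels. The series concerns tumour cells that fire action potentials, but the matrix names neither its genes nor its cells, so the expression of neuronal, glial or channel genes could not be read from it and no comparison of spiking with silent cells was possible. The values below describe how many genes were detected in the cells, how the counts were spread over genes and how the cells resembled one another. They come from cells of a pooled matrix and carry no test between groups.

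The patched cells held between 32579 and 18733378 counts, with a median of 2616041. The columns fell into 3 consecutive blocks that differed in depth. Columns 1 to 31 had a median of 886334 counts, columns 32 to 59 a median of 2406854.5 and columns 60 to 95 a median of 10615076.5. The cut with the least spread of totals lay after columns 31 and 59. The same cut was the only one of 4371 cuts into 3 stretches at which every gene was detected in every stretch, and moving either edge by 1 column left 12 to 61 genes absent from a stretch. These blocks of 31, 28 and 36 cells were read from the matrix, and the labels, which give 1 group, do not name them as groups. The 2 cells below the depth filter, columns 15 and 19, held 33798 and 32579 counts and were both in the first block.

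Kept cells had a median of 4324 genes at 1 count or more (quartiles 3413 and 5563, range 2470 to 9388, 93 cells). The median was 3453 at 1 CPM and 3095 at an equal depth of 100000 counts. The number at 1 count or more did not follow depth across blocks. The second block had the highest median, 5565.5 genes, against 3519 in the first block and 4149.5 in the third, which was sequenced most deeply. At an equal depth of 100000 counts the medians were 3144 genes in the 29 kept cells of the first block, 4759 in the 28 cells of the second and 2531 in the 36 cells of the third. The ranges overlapped, from 2223 to 5658 genes in the first block, 2584 to 8048 in the second and 1171 to 5720 in the third. The third block therefore ranked second by all counts and last at equal depth. The richest cell, column 56, had 8048 genes at equal depth although its total of 403410 counts was the lowest of its block. Of its 9388 genes at all counts, 3910 had counts of 1 to 10, where the median of its block was 655.5. The poorest, column 66, had 1171 genes at equal depth from a total of 8671686 counts.

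**Figure D1:**
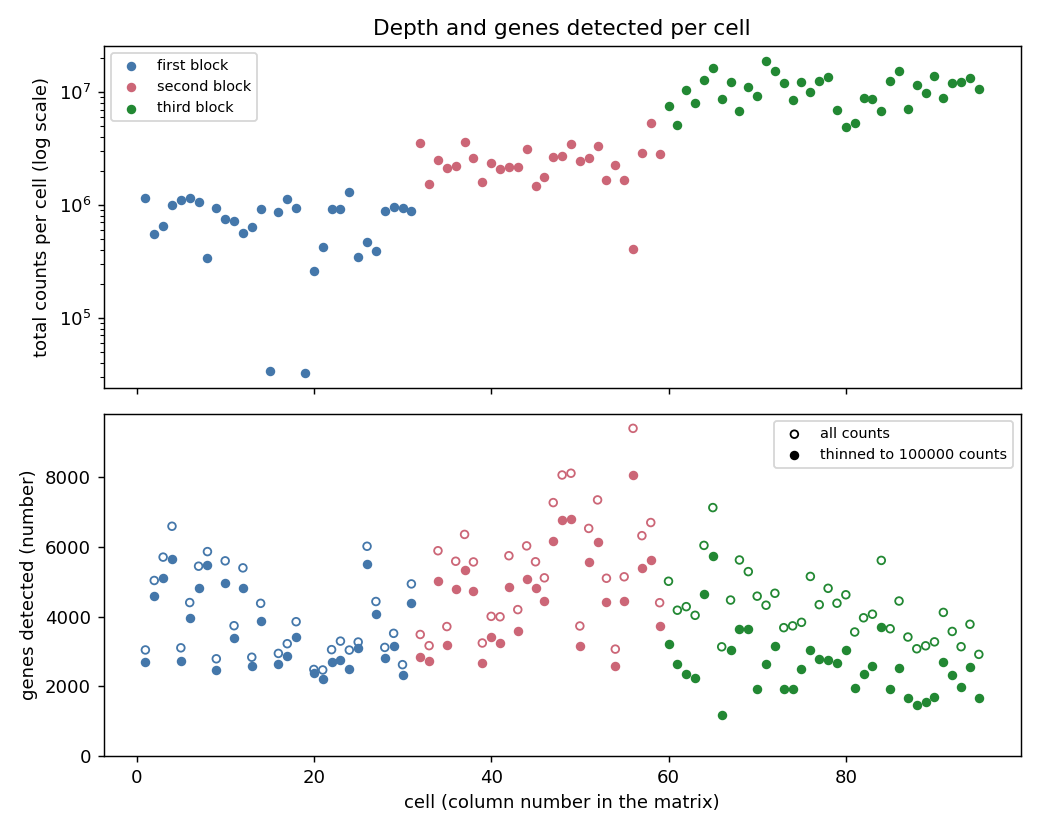
Total counts per cell on a log scale (upper panel, 95 cells) and genes detected per kept cell (lower panel, 93 cells; open circles all counts, filled circles after thinning to 100000 counts), by column number and coloured by block. Totals rise in steps after columns 31 and 59, while genes detected at equal depth are highest in the second block, with a median of 4759, and lowest in the third, with a median of 2531.

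Counts were spread over many genes in each cell. The smallest set of genes that held 50% of a cell's counts numbered a median of 389 genes (range 160 to 865, 93 cells). By block these medians were 386, 581 and 325.5 genes. The 50 most abundant genes of a cell took a median of 17.9% of its counts, with a range from 13% to 31%. A single gene, that of row 7916, had the highest count in 73 of the 95 cells. Its median level was 24232.5 CPM over the kept cells, with a range from 78.0 to 113141.5 CPM. Its median was 19486.9 CPM in the first block, 22837.1 CPM in the second and 29813 CPM in the third.

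Few genes were detected in all cells. Of the 14165 genes, 13 had a count in every cell and 3 reached 10 CPM in every kept cell. A level of 10 CPM was reached by 1510 genes in at least 50% of the kept cells, and by 2165 genes in only 1 to 5 of them. A gene was detected in a median of 26 of 95 cells (quartiles 13 and 43). Overall detection was 31.7% of the matrix. At this sampling a gene at 0 in a cell of the first block was compatible with up to 3.38 CPM at the median depth. In the third block the value was 0.283 CPM (each value 2 times as high if both reads of a pair were counted). By counting error alone, a 0 thus left more room for a low transcript in the shallower cells. Absence was not shown to be firmer in the third block, which had the fewest genes at 10 CPM (median 2440.5, against 3065 in the first and 4613 in the second).

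Counts in the third block formed 2 separate groups of values. There, 33.1% of the values above 0 lay between 1 and 10, only 8.65% lay between 11 and 100, and 40.5% exceeded 1000. In the first and second blocks values of 1 to 10 made up 20.1% and 13.9%, and most counts lay in 1 broad peak; the second block also had a small peak at counts of 2 to 3, with 5.35% of its values. A cell of the third block held a median of 1474.5 values of 1 to 10, against 624 in the kept cells of the first block and 655.5 in the second. At a threshold of 5 counts the median number of genes in the third block fell from 4149.5 to 2928.5, and at 1 CPM it was 2746.5.

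**Figure D2:**
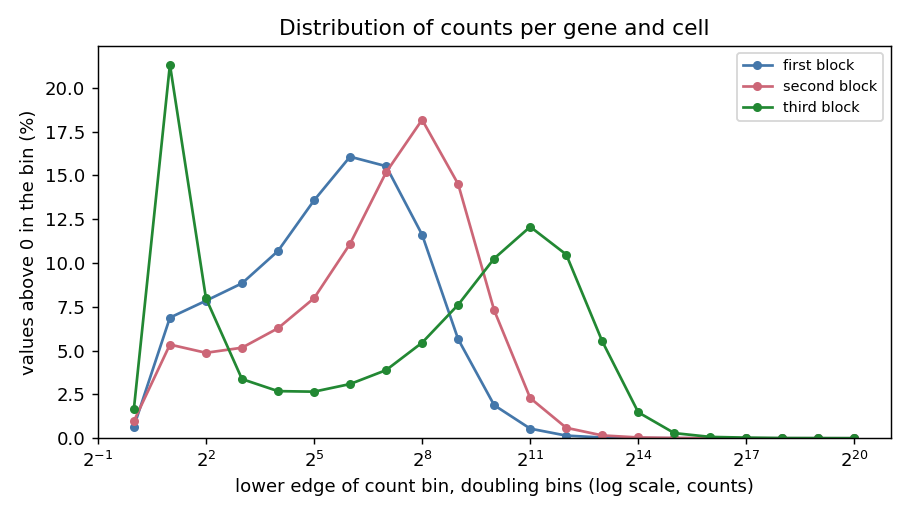
Share of values above 0 (percent, vertical axis) in doubling bins of the count per gene and cell (log scale, horizontal axis), one line per block over all its cells. The third block has a peak at counts of 2 to 3, with 21.3% of its values, and another in the bin that starts at 2048, with 12.1%.

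The cells were only moderately alike. Over 4278 pairs of kept cells the median correlation across genes was 0.24, with a lowest value of 0.10. The closest pair, columns 48 and 49, reached 0.59, so no kept column was a copy of another kept column. Cells of the same block resembled each other in the first block (median r 0.30) and the second (0.31) more than cells of those blocks resembled each other across blocks (0.26). In the third block the median within the block and those to the other blocks were all 0.23. The most similar cell of a given cell lay in its own block for 77 of 93 cells, where block sizes alone give 30.7. This held for 23 of 29 cells of the first block, 27 of 28 of the second and 27 of 36 of the third, and the total was again 77 at equal depth. Block and biological origin cannot be told apart here, because the columns carry no donor or tumour.

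The cells divided into 2 clusters of almost equal size. Both had cells in each block, but only 2 of the 28 cells of the second block were in cluster 2. Cluster 1 held 47 of 93 cells (50.5%, exact binomial 95% interval 40.0 to 61.1) and cluster 2 held 46. Cluster 1 made up 12 of 29 cells in the first block (41.4%, 23.5 to 61.1), 26 of 28 in the second (92.9%, 76.5 to 99.1) and 9 of 36 in the third (25%, 12.1 to 42.2). Cells of cluster 1 had more genes detected at equal depth than those of cluster 2, with medians of 4431 and 2633.5. Within blocks the medians were 4701 against 2750 in the first, 4803.5 against 2753 in the second and 3039 against 2352 in the third, and the ranges of the 2 clusters overlapped in every block. The mean silhouette was 0.258 for 2 clusters and between 0.20 and 0.23 for 3 to 8, so the division was shallow. With values centred within blocks the highest silhouette was at 6 clusters. Neither cluster can be given a cell type without gene names.

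**Figure D3:**
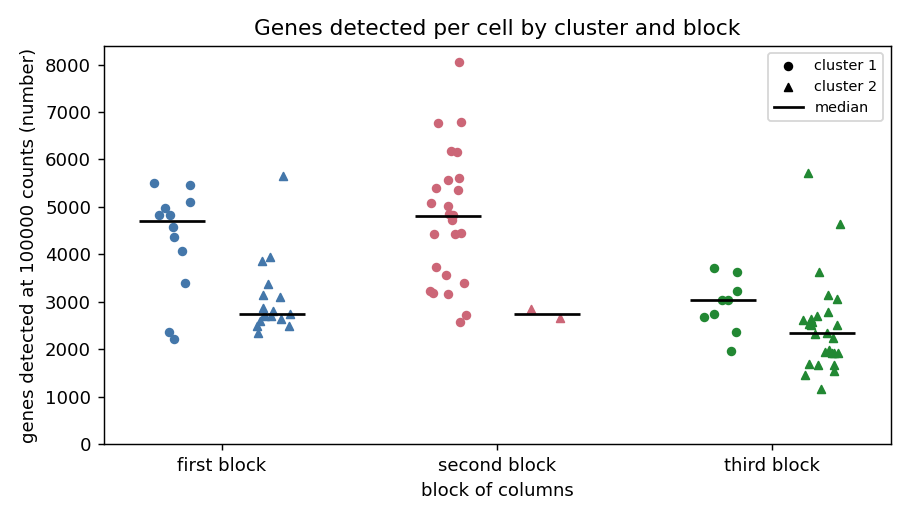
Genes detected per cell at 100000 counts (vertical axis) for the 93 kept cells, by block (horizontal axis and colour) and cluster (circles cluster 1, triangles cluster 2); black lines are medians and points are spread sideways for legibility. Cluster 1 lies higher in the first block, with medians of 4701 and 2750, and the clusters overlap in all blocks.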

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

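The other settings listed beforehand for marker and channel lists could not be run, because the rows carry no gene names. No paired analysis was possible because there is 1 group. Comparisons of nearest cells, leading genes and low values were chosen after seeing the data, alternatives included. Of 61 alternatives, 9 could not change their result, because they removed or added no cell or kept the division by construction. Of the other 52, 45 left their result the same, which for medians meant within 1 SD between cells, for low value ratios within 1 SD between strata of genes, and for counts within 1.5 times. These limits are wide. The SD between cells is the spread of single cells, and a fall of the median from 4324 to 3095 genes counted as the same. The 45 therefore do not measure how stable a median is. The number of clusters was 2 in the main analysis and under 1000 or 4000 variable genes, 10 or 25 components, k-means, no cell filter and thinned counts, and moved to 6 with values centred within blocks; the cause was not tested. At least 89 of the 93 cells kept their side under these alternatives, and 84 with centring, where each cluster was set to the side of most of its cells; 4 or 6 clusters are cut from the same tree and keep all 93 by construction. The median of 4324 genes became 3377 at a count of 5, 3453 at 1 CPM, 4283 without the cell filter and 3095 at equal depth. In the third block alone the median of 4149.5 genes moved to 2928.5, 2746.5 and 2531 under a count of 5, 1 CPM and thinning, so genes detected at 1 count are not a usable measure there. The stricter filter removed no further cell, so it tested nothing. The most similar cell lay in its own block for 77 to 83 of 93 cells under 4 other measures, and for 79 of 95 without the cell filter. By counting error alone, depth limits the first block most, where a count of 0 allows up to 11.6 CPM in the shallowest kept cell.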

Other observations

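The tests of explanations in this part were chosen after the patterns were seen, and the one with cells matched on genes detected was written down before its result was known. No named gene or cell type can be described, since the matrix gives row numbers alone.

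Each block was also clustered on its own with the number of clusters set to 2, so whether a block divides at all was not tested. The sides so formed matched the pooled clusters in the first and the third block, and not in the second. Their mean silhouettes were low, at 0.233 in the first block, 0.197 in the second and 0.149 in the third. Clustering the first and the third block each on its own placed 62 of their 65 cells on the same side as the pooled clusters. Putting each block in its larger cluster would give 44, so in these 2 blocks the division does not simply follow the block. Both clusterings used the same cells and counts, so agreement was likely from the start. The 62 cells therefore do not show how much of the division comes from the blocks, and they leave out the second block. Of the 100 leading genes on the side with more genes per cell, 22 were shared between the first and the third block, and of the 100 on the other side 26 were shared, against 2.43 and 2.19 for lists matched on mean level; in pairs of cells matched on genes detected (3 pairs in the first block and 6 in the third) 17 and 13 were still shared, against 1.99 and 2.03, which argues against the number of genes per cell as the whole cause. The second block, with 2 cells in cluster 2, split differently. Of its 28 cells 17 matched, fewer than the 26 in its larger pooled cluster. On the sides with more and with fewer genes, it shared 5 and 3 of 100 with the first block (2.80 and 1.26 for matched lists). With the third it shared 1 and 4 (2.79 and 0.849). With the leading 50 genes it shared 3 and 0 with the first block (0.777 and 0.343). With the third these were 0 and 0 (0.865 and 0.165). With the leading 200 it shared 19 and 6 with the first (9.59 and 4.32) and 7 and 5 with the third (8.59 and 3.61). On the side with more genes, sharing was above the matched number at every length with the first block. With the third block it was below that number at every length. On the side with fewer genes, sharing above the matched numbers depended on the length of the lists. Across genes, the differences between the sides correlated at r 0.402 between the first and the third block, 0.196 between the first and the second, and -0.022 between the second and the third. A kind of cell present in the first and the third block may account for the rest as a hypothesis, while RNA quality and RNA from neighbouring cells drawn into the pipette stay open, since both need gene names to test.

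The surplus of values of 1 to 10 in the third block may come from reads assigned to the wrong cell of that block. Among genes above 10 in the same number of its cells, the share of values of 1 to 10 in the remaining cells was 2.26 times as high for the genes with the largest totals (top 25% of genes) as for those with the smallest (bottom 25%), and it was higher in 10 of 10 strata. The ratio was 0.518 in the first block and 0.479 in the second. The blocks were compared at the same counts and not at the same CPM. Median totals were 886334 in the first block, 2406854.5 in the second and 10615076.5 in the third. The contrast between blocks therefore does not by itself count for the explanation. In the third block the ratio was 1.69 by the block's own totals at a matched level in the other blocks, against 1.06 the other way round. Deeper sequencing of each cell's own library stays open. The deeper 18 cells held 0.770 times the median number of such values of the shallower 18 (1188.5 against 1543), but depth also lifts a cell's own values above 10, and the same ratio was 0.565 in the first block and 1.01 in the second, so it decides nothing. Carry-over between wells and chimeric molecules formed in pooled amplification would give the same pattern and stay open, and low but real expression was not excluded for any single gene.

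The rows hold only genes found in each of the 3 blocks, as if they were the genes shared by 3 separately made tables. With the edges of the blocks set by the totals alone, 0 genes were absent from a block, where placing each gene's cells at random would leave 688 absent from at least 1 block. This fits the explanation that only genes found in each of 3 separately made tables were kept. The 0 is the pattern itself and was known when the explanation was written. It shows that rows depend on the blocks, and not that the tables were made separately. A gene expressed in cells of 1 block alone would then be missing, which could hide markers of a rare cell type. The sample titles also run in 3 series, of 31, 28 and 36 samples, the sizes of the 3 blocks, but columns were not assigned to samples on that ground.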
